A study of Mus musculus with 12 samples.

How the data were processed

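Polyadenylated RNA of mouse hippocampal neural stem cells was measured by paired-end RNA sequencing in 12 libraries, 4 each from passage 2 (P2), passage 10 after culture with phosphate-buffered saline (P10 PBS) and passage 10 after culture with small extracellular vesicles of embryonic stem cells (P10 EV). The authors deposited 1 table with raw counts per gene and with FPKM, the counts scaled by gene length and by the total of the library, for each library; a second deposited table, which repeats these values, adds annotation per gene, from which only the KEGG pathway names were used. The cells of both tables were compared and 0 differed. HISAT2 2.0.4 and StringTie 1.3.0 are listed by the authors without a role, and the program that counted the reads and the genome build are not given in the sources used here. Of 34745 gene identifiers in the table, 34267 are in GENCODE M21, the annotation of mouse build GRCm38, and 80.79% of these have the same chromosome, start and end there, so coordinates are printed as deposited. The FPKM of every library was checked against its counts: the gene length that the pair implies differed between libraries by a ratio of at most 1.0008.

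Columns were assigned to samples by the library names in the labels, which left 0 columns unmatched. Total counts ranged from 10736538 to 16807647 per library. Genes were kept by filterByExpr of edgeR 4.0.16 with a minimum count of 10, which left 16058 of 34745 genes; 10536 genes had no read in any library. Libraries were scaled by TMM factors, which lay between 0.941 and 1.038. Levels are given as CPM, the count scaled by the TMM-adjusted total of its library. The CPM of liver transcripts are the exception, scaled by the unadjusted total over all genes. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries together in edgeR (9 residual degrees of freedom), each pair of groups was contrasted, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested; a gene was called at an adjusted p under 0.05. Adjusted p-values of genes come from this edgeR fit unless another tool is named. Fold changes are log2 values, the first-named group over the second, with their standard error (SE).

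Before the data were examined, the groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed. Of the gene lists, 41 were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01. They were tested again with a correlation estimated from all 12 libraries. P-values were adjusted over the lists of a comparison. Fry, a rotation test that asks whether the genes of a list move on balance in 1 direction, was run beside camera. The genes named per comparison are the 8 largest rises and 8 largest falls among called genes whose 4 libraries in 1 group all lie above the 4 of the other, with a mean of at least 5 CPM in the higher group and a symbol that is not a model number. For each list discussed, 2 to 4 called members with the smallest adjusted p are named, or up to 2 of the most expressed where none was called. Some genes that this rule takes are not reported here. The genes in the study's title were always named: Smad1 to Smad7, Smad9, Myt1, Egln3 and Sirt1. KEGG pathways of 10 to 500 genes were tested for over-representation among called genes against the tested genes with a pathway.

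Whether replicate numbers pair the libraries was examined from the deviations of libraries from their group means, correlated over genes between libraries of the same number. Between P10 EV and P10 PBS these correlations were 0.37, 0.148, 0.138 and 0.208, and 3 of 4 libraries matched their own number best. Between P10 EV and P2 they lay between 0.087 and 0.187, and between P10 PBS and P2 between -0.084 and 0.211. The library names carry the same culture code for a replicate number in all 3 groups, and sex-linked transcripts matched by number, but the labels do not say whether a code stands for 1 animal. The main fit took the 12 libraries as independent and did not use this match, and the block on replicate number was run only as an alternative. The p-values of the main fit therefore ignore any pairing and measure only the spread between these samples.

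The alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), no filter on low counts, the 8 libraries of a comparison alone, a block on replicate number, a fold change of at least 2, and leaving out each library in turn. Alternatives chosen after seeing the data were a term for 4 libraries with liver transcripts, the omission of these 4 libraries, and a term for the sex of the culture. All 35 splits of the 8 libraries of a comparison into 4 and 4 were refitted. Comparisons that share libraries were set against simulated libraries and against fits with the shared libraries divided; those for DESeq2 and for the shared P2 libraries were added after seeing the data. The pipeline was tested on simulated data with known changes. Each comparison had a single draw with its own randomly picked genes, so the shares recovered do not rank the comparisons by power. At a true fold of 2 edgeR recovered 28.4% of changed genes in the draw for P10 PBS against P2. There edgeR recovered 44.8% in the draw for P10 EV against P10 PBS and 38.8% in that for P10 EV against P2. At a true fold of 4 it recovered 80.3%, 81.8% and 84.8%. Computations used R 4.3.3, Python 3.11, pandas 2.3.3 and matplotlib 3.10.9. Reads were not realigned and single transcripts were not analysed here.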

Results

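RNA was sequenced from neural stem cells of the hippocampus of C57BL/6 mice, grown in medium with B27 supplement, EGF, bFGF and heparin. Early cultures were sampled at passage 2 (P2, n = 4 libraries). Late cultures were sampled at passage 10 after treatment from passage 2 on with small extracellular vesicles of embryonic stem cells (P10 EV, n = 4), which are membrane particles shed by those cells, or with an equal volume of saline (P10 PBS, n = 4). The title of the study states that it asked whether the vesicles rejuvenate ageing stem cells through SMAD proteins, which carry TGF-beta and BMP signals to the nucleus, and an axis of Myt1, Egln3 and Sirt1. In the order of their replicate numbers, the P2 libraries held 14004946, 14172913, 12267435 and 11951034 counts. The P10 PBS libraries held 15610366, 10736538, 10775276 and 13820495 counts, and the P10 EV libraries 16807647, 11652364, 11727690 and 15541616. Between 19698 and 20562 genes had at least 1 read per library.

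The 4 early cultures differed from one another more than the late cultures did. On the first principal component, which held 30.1% of the variance, P2 replicate 1 lay at -27.5 and P2 replicates 2, 3 and 4 at 22.1, 86.5 and 52.8, whereas the 8 late libraries lay between -26.9 and -5.6. Replicates 1 and 2 expressed Xist, the transcript of the silenced X chromosome, at 28794 to 49377 counts in every group. Replicates 3 and 4 expressed Y-linked genes instead, at 1333 to 3124 counts in sum, in every group. Transcripts of liver were found in P2 replicate 1, P2 replicate 2, P10 PBS replicate 1 and P10 EV replicate 1, where Alb (albumin) lay between 15.5 and 20.7 CPM against at most 0.145 CPM in the other libraries.

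The comparison of P10 PBS with P2 asks what changed with passage in the absence of vesicles. Transcripts of imprinted genes, which are expressed from the chromosome of 1 parent, were lower in late cultures. Ndn (ENSMUSG00000033585; chromosome 7, 62348277 to 62349928), which encodes the growth suppressor necdin, fell from 147 ± 14.4 CPM (SD, n = 4) at P2 to 36.7 ± 3.04 CPM, a log2 fold change of -2.0 ± 0.16 (SE) with an adjusted p of 0.000237. Grb10 (ENSMUSG00000020176; chromosome 11), an adaptor that restrains insulin and growth factor receptors, fell from 67.9 ± 43.2 to 0.538 ± 0.208 CPM (-6.91 ± 0.82, adjusted p = 0.00327). Magel2 and Mkrn3, neighbours of Ndn on chromosome 7, had fold changes of -5.53 ± 0.90 and -1.03 ± 0.19, and Cdkn1c, an inhibitor of cyclin-dependent kinases that is also on the senescence list, of -2.50 ± 0.49. Of 26 imprinted genes tested, 5 fell, 0 rose and 21 did not pass; adjusted over the list alone, 9 fell and 1 rose. The list fell as a whole, with 21 of 26 members below 0, a median of -0.29 and a mean of -0.94 (camera adjusted p = 1.05e-07; adjusted p = 0.00484 with an estimated correlation). Ndn and Grb10 kept their calls whichever library was left out, and that of Grb10 was lost with limma-voom (adjusted p = 0.0607). The adjusted p reached 0.0719 for Magel2, 0.108 for Mkrn3 and 0.108 for Cdkn1c over the settings; the call of Magel2 was lost without P10 PBS replicate 1. Those of Mkrn3 and Cdkn1c were lost without P2 replicate 3, P2 replicate 4, P10 PBS replicate 1 or P10 PBS replicate 4, that of Mkrn3 also without P10 PBS replicate 3, and that of Cdkn1c also without P2 replicate 2 or P10 PBS replicate 2.

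The neuronal lineage list fell, and 2 regulators of the dorsal forebrain fell. Emx2 (ENSMUSG00000043969; chromosome 19), a homeobox regulator of hippocampal and cortical growth, fell from 25.1 ± 2.73 to 8.98 ± 2.05 CPM (-1.48 ± 0.18, adjusted p = 0.00329), and Lhx2, a LIM-homeobox gene that specifies cortex, from 50.8 ± 9.33 to 26.6 ± 5.93 CPM (-0.93, adjusted p = 0.0304). Of 32 genes of the neuronal lineage, 4 fell, 0 rose and 28 did not pass, and 8 fell adjusted over the list alone. They were Myt1, a zinc-finger factor of neuronal commitment, Dpysl3, a regulator of axon growth, Bcl11b, a transcription factor of projection neurons, and Insm1, a factor of basal progenitors; their fold changes were -1.28, -0.89, -0.96 and -1.99. The neuronal lineage list had 25 of 32 members below 0 and a median of -0.38 (adjusted p = 1.53e-06; adjusted p = 0.0394 with an estimated correlation). In the dorsal telencephalon list, 2 of 9 genes fell (2 adjusted over the list alone), with a median of -0.13 and an adjusted p of 0.0342, or adjusted p = 0.386 with an estimated correlation. That list was not called when any of 8 libraries was left out, with adjusted p-values of 0.0596 without P10 PBS replicate 1, 0.574 without P2 replicate 3 and values between these without the others. Emx2 kept its call whichever library was left out. Myt1, Dpysl3, Bcl11b, Insm1 and Lhx2 each lost the call without P10 PBS replicate 3, and each also without 4 or 5 of the other libraries P2 replicates 2 to 4 and P10 PBS replicates 1, 2 and 4; the highest adjusted p over the settings was 0.101, 0.108, 0.104, 0.107 and 0.112. With a block on replicate number the adjusted p of Lhx2 was 0.061, that of Dpysl3 0.052 and that of the dorsal telencephalon list 0.0773.

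Oligodendrocyte genes were lower in late cultures, and early cultures were unequal in them. Of 29 genes of the oligodendrocyte lineage, 2 fell, 0 rose and 27 did not pass; adjusted over the list alone, 12 fell and 1 rose. Sox10, the transcription factor that drives the lineage, fell from 71.8 ± 52.4 to 3.41 ± 1.62 CPM (-4.39 ± 0.80, adjusted p = 0.0243), but P2 replicate 1 held 5.28 CPM and the other early libraries 55.1 to 119 CPM. Matn4, a matrix protein, had a fold change of -3.66. The oligodendrocyte lineage list had 23 of 29 members below 0 and a median of -0.72 (adjusted p = 1.02e-06; adjusted p = 0.452 with an estimated correlation). Its mean deviation per library was -0.652 in P2 replicate 1 and 1.10, 0.967 and 0.254 in P2 replicates 2, 3 and 4, against -0.494 to -0.171 in P10 PBS. The calls of Sox10 and Matn4 were lost without P2 replicate 3, P2 replicate 4, P10 PBS replicate 1, P10 PBS replicate 3 or P10 PBS replicate 4, that of Sox10 also without P10 PBS replicate 2 and that of Matn4 also without P2 replicate 2. They reached adjusted p-values of 0.184 and 0.131 over the settings.

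The extracellular matrix list was lower in late cultures, with 3 called genes of 49. Thbs2 (thrombospondin) fell from 9.44 ± 2.75 to 0.735 ± 0.662 CPM (-3.63 ± 0.55, adjusted p = 0.0127), and Fbln2 (fibulin) from 603 ± 92.4 to 291 ± 43.6 CPM (-1.05, adjusted p = 0.0153). Mmp2, a gelatin-degrading protease, fell from 9.9 ± 4.73 to 1.11 ± 0.68 CPM (-3.18 ± 0.47, adjusted p = 0.0119), and Mmp14, a membrane protease, from 143 to 29 CPM (-2.29). In the list, Thbs2, Fbln2 and Matn4 fell and 46 genes did not pass; adjusted over the list alone, 9 fell and 1 rose. The list had a median of -0.19 and an adjusted p of 0.0125 (adjusted p = 0.708 with an estimated correlation), and was not called without P2 replicate 2 (adjusted p = 0.522). The call of Fbln2 was lost without P10 PBS replicate 1 (highest adjusted p over the settings 0.0514). Mmp2, Mmp14 and Gdf15, a stress-induced cytokine, were the 3 genes that fell of 28 factors secreted by senescent cells, the SASP list, which was not called (median -0.06, adjusted p = 0.625). Gdf15 and Mmp14 lost their calls without P2 replicate 3, P2 replicate 4, P10 PBS replicate 1, P10 PBS replicate 2 or P10 PBS replicate 3, and Gdf15 also without P2 replicate 2 or P10 PBS replicate 4, with adjusted p-values of up to 0.0988 and 0.133 over the settings.

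Transcripts of DNA replication and of cholesterol synthesis were higher as lists, with 0 members called by edgeR. The S phase list had 39 of 40 members above 0 and a median of 0.68 (adjusted p = 8.28e-15; adjusted p = 0.493 with an estimated correlation). Rrm1, a subunit of ribonucleotide reductase, lay at 257 ± 138 CPM at P2 and 410 ± 34 CPM at P10 PBS (0.67, adjusted p = 0.328), and Mcm2, of the replicative helicase, had a fold change of 0.63. The S phase score was 0.563 in P2 replicate 1 and -0.327, -1.80 and -1.23 in P2 replicates 2, 3 and 4, against 0.171 to 0.331 in P10 PBS. The cholesterol synthesis list had 24 of 25 members above 0 and a median of 0.89, with 0 called over all genes and 14 called adjusted over the list alone (adjusted p = 1.8e-13; adjusted p = 0.452 with an estimated correlation). Hmgcs1, which forms the precursor of mevalonate, lay at 695 ± 286 CPM at P2 and 1360 ± 496 CPM at P10 PBS (adjusted p = 0.176). The cholesterol score was -1.20 and -0.777 in P2 replicates 3 and 4 and -0.002 and 0.229 in P2 replicates 1 and 2. In P10 PBS it was 0.72 and 0.716 in replicates 3 and 4 and 0.071 and -0.003 in replicates 1 and 2.

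Among single genes that rose, Frk (ENSMUSG00000019779; chromosome 10), a Src-related kinase, went from 1.8 ± 0.729 to 8.79 ± 1.32 CPM (2.29 ± 0.29, adjusted p = 0.00408). St6gal2, a sialyltransferase, rose from 8.6 ± 4.51 to 38.5 ± 10.6 CPM (2.17), Palmd (palmdelphin) from 3.61 ± 1.0 to 15.8 ± 3.88 CPM (2.12), and Kank4, of the actin cytoskeleton, from 6.63 ± 3.12 to 24.9 ± 1.07 CPM (1.91). Fold changes were 1.87 for Foxc1, a forkhead factor of meninges and vessels, 2.07 for Ankrd34c, 2.09 for Casp12, a caspase of the endoplasmic reticulum, and 2.80 for Cnpy1. Hoxa5, a homeobox gene of the posterior body axis, was called with 1 pooled count at P2, 63 at P10 PBS and 50 at P10 EV. H2-Q4, a class I histocompatibility gene, rose from 1.73 to 6.13 CPM; it was the 1 called gene of 15 in its list, whose median of -0.07 and mean of 0.15 differed in sign (test upward, adjusted p = 0.701). Further falls were those of Moxd1 (-4.39), Grin2c, a glutamate receptor subunit (-3.78), Kcne1l (-3.65) and Myh14, a non-muscle myosin (ENSMUSG00000108439, 1 of 2 identifiers with this symbol; -3.15). With a block on replicate number, the adjusted p was 0.0606 for Cnpy1, 0.0523 for Casp12, 0.0677 for Myh14 and 0.0561 for H2-Q4.

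In all, 61 genes rose and 88 fell at P10 PBS against P2 (123 of these 149 by a fold of at least 2). The libraries of both groups did not overlap in 916 of 16058 genes, or 5.7%. Interchangeable libraries would give 2.86% on average, but the spread of this share over splits was not computed, so it is no test of chance. DESeq2 called 592. Without 1 library the count was 1206 without P2 replicate 1, 76 without P2 replicate 3, 62 without P2 replicate 4, 41 without P10 PBS replicate 1, 44 without P10 PBS replicate 3 and 72 without P10 PBS replicate 4. Of 32 named calls, 20 were lost without P10 PBS replicate 1, 18 without P10 PBS replicate 3, 18 without P2 replicate 3, 15 without P2 replicate 4, 14 without P10 PBS replicate 4, 13 without P10 PBS replicate 2 and 6 without P2 replicate 2, and 10 kept their call whichever library was left out: Frk, Palmd, Kank4, Foxc1, Grb10, Thbs2, Mmp2, Emx2, Hoxa5 and Ndn. Of 41 lists, 6 rose and 11 fell, of which 3 were called with an estimated correlation: the imprinted, neuronal lineage and Hox lists, the last with 2 genes tested (adjusted p = 1.53e-06, or 0.0394 with an estimated correlation). Each P2 library held 2 to 6 counts over 29 Hox genes, so a Hox gene could pass the count filter only through the late groups. The upward direction of that list was therefore set by the filter. The autophagy and lysosome list fell with a median of -0.21 (adjusted p = 0.0244; adjusted p = 0.947 with an estimated correlation), but was not called without P2 replicate 3, P2 replicate 4, P10 PBS replicate 3 or P10 PBS replicate 4 (adjusted p = 0.987, 0.07, 0.0571 and 0.119). The senescence list fell with a median of -0.25 and 1 called gene of 16, Cdkn1c (adjusted p = 0.0488; adjusted p = 0.386 with an estimated correlation), and was not called without P2 replicate 1, P2 replicate 2, P10 PBS replicate 2, P10 PBS replicate 3 or P10 PBS replicate 4 (adjusted p = 0.107, 0.176, 0.179, 0.0571 and 0.0667). Lists of neural stem cells (median -0.06, adjusted p = 0.145), astrocytes (-0.25, 0.286), HIF targets (0.27, 0.459) and oxidative phosphorylation (0.04, 0.313) were not called, nor were TGF-beta and BMP targets, whose median of -0.04 and mean of -0.05 differed in sign from the test (adjusted p = 0.946). No KEGG pathway was over-represented among genes that rose or fell; the smallest adjusted p was 0.963. Without the 4 libraries with liver transcripts 2320 genes were called, and the dorsal telencephalon, extracellular matrix and senescence lists were not (adjusted p = 0.562, 0.146 and 0.277). That left only replicates 3 and 4 in P2, both with Y-linked transcripts. It also removed P2 replicate 1, whose omission alone gave 1206 genes, so the change cannot be credited to the liver transcripts.

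**Figure D1:**
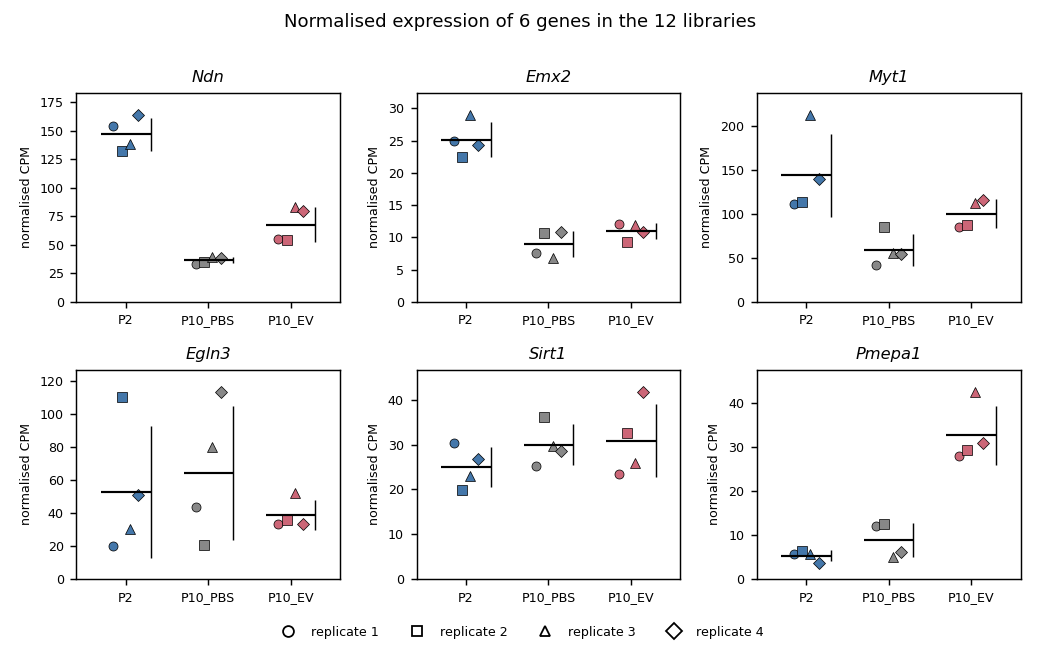
Normalised expression (CPM, linear axis from 0) of 6 genes in each of the 12 libraries, with 1 marker shape per replicate number, a line at the group mean and a bar of 1 SD. Ndn lay at 147 ± 14.4 CPM at P2, 36.7 ± 3.04 CPM at P10 PBS and 67.9 ± 15.5 CPM at P10 EV, and Egln3 and Sirt1 overlapped between the groups.

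The genes of the study's title were read in all 3 groups. Myt1 (ENSMUSG00000010505; chromosome 2) lay at 144 ± 47.3 CPM at P2, 59.3 ± 18.2 CPM at P10 PBS and 101 ± 16.5 CPM at P10 EV (SD, n = 4 each). It fell at P10 PBS against P2 (-1.28 ± 0.25, adjusted p = 0.0284). The fold change with vesicles was 0.76 ± 0.24 (adjusted p = 0.55), and over the settings it lay between 0.61 and 0.99 with adjusted p-values from 0.217 to 1; P10 EV against P2 gave -0.52 (adjusted p = 0.26). Egln3 (ENSMUSG00000035105; chromosome 12), a prolyl hydroxylase of the oxygen-sensing pathway, lay at 52.9 ± 40.3, 64.4 ± 40.8 and 38.7 ± 9.11 CPM, with a fold change of -0.74 ± 0.53 with vesicles (adjusted p = 0.813). Sirt1 (ENSMUSG00000020063; chromosome 10), a NAD-dependent deacetylase, lay at 25 ± 4.51, 30 ± 4.58 and 30.9 ± 8.19 CPM, with a fold change of 0.05 ± 0.20 with vesicles (adjusted p = 0.975). Smad1, Smad2, Smad3, Smad4, Smad5, Smad7 and Smad9 had fold changes from -0.51 to 0.08 with vesicles and from -0.23 to 0.29 at P10 PBS against P2, and 0 of them were called by edgeR in any comparison. Smad4, the partner shared by TGF-beta and BMP signals, lay at 135, 115 and 117 CPM. Smad6 had 72 counts in the 12 libraries and was not tested. These are RNA levels of the cultures and do not measure SMAD proteins, of the cells or of the vesicles. The call of Myt1 was lost without P2 replicate 3, P2 replicate 4, P10 PBS replicate 1, P10 PBS replicate 3 or P10 PBS replicate 4, with a highest adjusted p of 0.101 over the settings. The list of 10 title genes was not called in any comparison (adjusted p = 0.946, 0.982 and 0.92), and at P10 PBS against P2 its median of 0.13 and its mean of -0.02 differed in sign, with the test pointing down.

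The comparison of P10 EV with P10 PBS asks what the vesicles changed at the same passage. No single gene passed the test. Lists of oxidative phosphorylation, glycolysis, HIF targets and astrocytes were lower at the preset correlation between genes, but none of them with an estimated correlation. The latter was estimated from all 12 libraries, with the unequal P2 libraries among them. It was not estimated from the compared libraries alone, so it need not hold for the late cultures. Of 76 oxidative phosphorylation genes, 71 lay below 0 with a median of -0.27 (adjusted p = 2.9e-13; adjusted p = 0.535 with an estimated correlation), and Atp5b, a subunit of ATP synthase, lay at 1830 CPM at P10 PBS and 1530 CPM at P10 EV. All 21 glycolysis genes lay below 0 (median -0.61, adjusted p = 8.58e-08; adjusted p = 0.535 with an estimated correlation), with Eno1 (enolase) at 1160 ± 418 and 800 ± 185 CPM and Pkm (pyruvate kinase) at 2490 and 1710 CPM. Among HIF targets, the genes switched on by low oxygen, 46 of 48 lay below 0 (median -0.63, adjusted p = 3.41e-08; adjusted p = 0.772 with an estimated correlation), with Ldha (lactate dehydrogenase) at 1050 ± 631 and 660 ± 182 CPM. Each list had 0 members called by edgeR over all genes. The HIF targets score was unequal within P10 PBS, at -0.374, -0.727, 0.751 and 1.16 in replicates 1 to 4, against -0.57, -0.076, 0.128 and -0.548 in P10 EV, so that replicate 2 was higher with vesicles. The glycolysis score was -0.07, -0.547, 0.59 and 0.944 in P10 PBS and -0.455, -0.007, 0.012 and -0.672 in P10 EV, again with replicate 2 higher. The OXPHOS nuclear score was lower with vesicles at all 4 replicate numbers, at 0.333, 0.043, -0.03 and 0.015 in P10 PBS and 0.006, -0.175, -0.108 and -0.283 in P10 EV.

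Astrocyte genes lay below 0 in 31 of 34 cases (median -0.54, adjusted p = 1.59e-09; adjusted p = 0.535 with an estimated correlation). The astrocyte score was lower with vesicles at all 4 replicate numbers without overlap, -0.225 to 0.604 in P10 PBS and -0.615 to -0.285 in P10 EV. Slc1a3, the glial glutamate transporter, lay at 2060 ± 425 CPM at P10 PBS and 1410 ± 127 CPM at P10 EV (-0.54, adjusted p = 0.67). Cholesterol synthesis genes lay below 0 in 25 of 25 cases (median -0.31, adjusted p = 6.83e-05; adjusted p = 0.772 with an estimated correlation), class I histocompatibility genes in 15 of 15 (median -0.39, adjusted p = 0.000535; adjusted p = 0.535 with an estimated correlation) and lysosomal genes in 34 of 37 (median -0.22, adjusted p = 6.83e-05; adjusted p = 0.772 with an estimated correlation). The autophagy and lysosome score was also lower at all 4 numbers without overlap, -0.085 to 0.161 in P10 PBS and -0.369 to -0.104 in P10 EV. The cholesterol synthesis score was higher with vesicles in replicate 1 (0.071 and 0.372), and the MHC class I score in replicate 2 (-0.034 and 0.081). Secreted factors of senescent cells, the SASP list, had a median of -0.34 (adjusted p = 0.0176; adjusted p = 0.535 with an estimated correlation), with Igfbp2, which binds insulin-like growth factors, at 1200 ± 388 and 739 ± 99.7 CPM. The SASP score was higher with vesicles in replicate 2 (-0.274 and 0.014). The SASP list was not called without P10 PBS replicate 1 or P10 EV replicate 1 (adjusted p = 0.141 and 0.0594). The list of sirtuins and SIRT1-linked genes had a median of -0.12 (adjusted p = 0.0176; adjusted p = 0.535 with an estimated correlation) and was not called without P10 PBS replicate 4 (adjusted p = 0.0593). The sirtuins and SIRT1-linked score was lower at all 4 numbers without overlap, -0.009 to 0.199 in P10 PBS and -0.196 to -0.049 in P10 EV. Without the 4 libraries with liver transcripts these last 2 lists were not called (adjusted p = 0.285 and 0.0504).

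Cell-cycle lists were higher with vesicles at the preset correlation, with 0 members called by edgeR. G2/M genes lay above 0 in 50 of 53 cases (median 0.20, adjusted p = 0.000354; adjusted p = 0.772 with an estimated correlation), with Mki67, a marker of cycling cells, at a fold change of 0.36 and Top2a, a topoisomerase, at 0.20. P10 EV replicate 4 stood apart in both genes. It held Mki67 at 861 CPM (other P10 EV libraries 468 to 515) and Top2a at 813 CPM (600 to 620). The groups overlapped in the G2/M phase score, at -0.093, -0.119, 0.264 and 0.25 in P10 PBS and 0.215, 0.149, 0.263 and 0.475 in P10 EV. S phase genes lay above 0 in 36 of 40 cases (adjusted p = 0.0176; adjusted p = 0.772 with an estimated correlation), but this list was not called without P10 PBS replicate 2 or P10 PBS replicate 4 (adjusted p = 0.0893 and 0.055). The S phase score was higher with vesicles at all 4 numbers without overlap, 0.171 to 0.331 in P10 PBS and 0.382 to 0.542 in P10 EV. Oligodendrocyte lineage genes had a median of 0.11 (adjusted p = 0.00227; adjusted p = 0.772 with an estimated correlation) and imprinted genes a median of 0.11 (adjusted p = 0.0211; adjusted p = 0.535 with an estimated correlation). The imprinted list was not called without P10 PBS replicate 2 (adjusted p = 0.0637). The imprinted score was higher at all 4 numbers with overlap, -0.511 to -0.218 in P10 PBS and -0.354 to 0.078 in P10 EV, and the oligodendrocyte lineage score was lower in replicate 2 (-0.171 and -0.198). Neural stem cell genes (median -0.05, adjusted p = 0.474), the neuronal lineage (0.11, 0.137), the senescence list (-0.17, 0.729) and TGF-beta and BMP targets (adjusted p = 0.258) were not called.

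By edgeR, 0 genes were called with vesicles, with a smallest adjusted p of 0.257, whereas 1163 had an unadjusted p under 0.05 (458 higher and 705 lower) and DESeq2 called 67 (30 higher and 37 lower). The libraries of both groups did not overlap in 1217 genes, 7.58% where interchangeable libraries would give 2.86% on average. The spread of this share over splits was not computed, so it is no test of a vesicle effect. Without P10 PBS replicate 2 and without P10 EV replicate 1 edgeR called 1 gene each. Of 41 lists, 5 rose and 11 fell at the preset correlation and 0 were called with an estimated correlation.

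**Figure D2:**
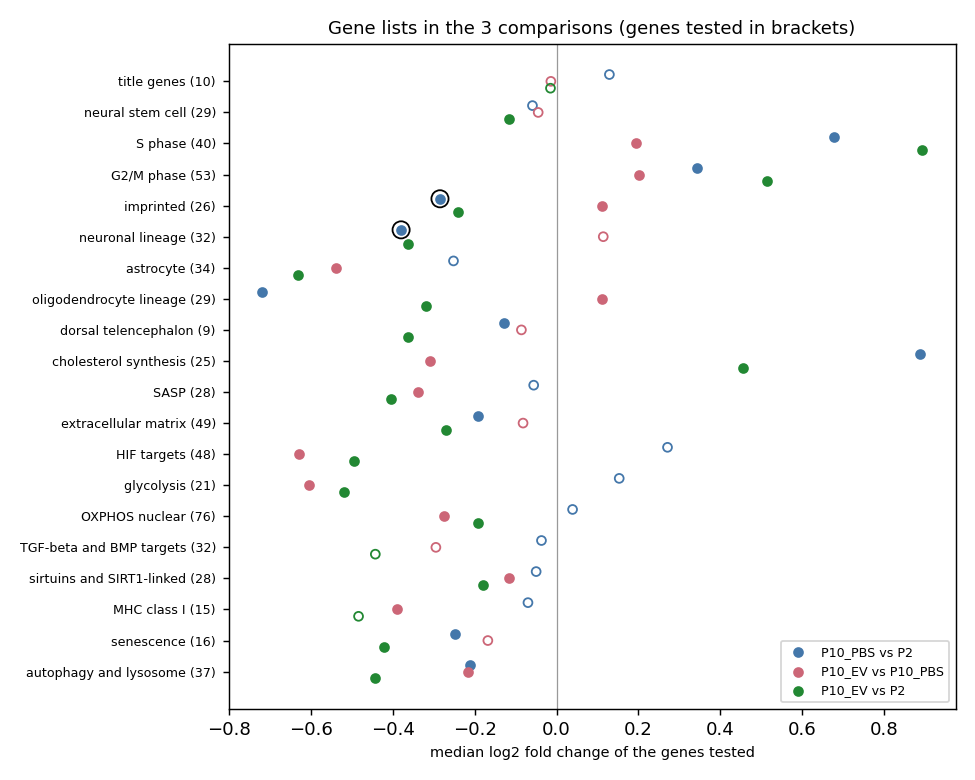
Median log2 fold change (horizontal axis) of the tested members of 20 fixed gene lists in each of the 3 comparisons; filled points have a camera adjusted p under 0.05, open points do not, and a black ring marks lists also called with an estimated correlation. The rings are on the imprinted and neuronal lineage lists at P10 PBS against P2, and the glycolysis median with vesicles was -0.61.

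Whether vesicles moved late cultures back towards early ones was examined over all tested genes. By edgeR, 0 genes were called in opposite directions at P10 PBS against P2 and at P10 EV against P10 PBS, because the latter had 0 calls; DESeq2 called 29 in opposite directions and 0 in the same direction. Of the 29, 10 were higher at P10 PBS and then lower with vesicles, and 19 were lower and then higher. Because P10 PBS enters both comparisons with opposite signs, opposite calls arise without any vesicle effect, and Fisher's exact test, which takes the lists as independent, is not used here. In 20 simulated sets with the passage effect and no vesicle effect, DESeq2 gave 1 to 7 opposite calls. Those sets differed from the data, with 1313 to 1529 DESeq2 calls at P10 PBS against P2 where the data gave 592. With vesicles they held 1 to 14 calls where the data gave 67, so they give no baseline for the 29. With the P10 PBS libraries divided between both comparisons in 6 ways, DESeq2 gave 0 to 16 opposite calls, with a mean of 6.5. In the same direction the divided fits shared 0 to 5 rises and 0 to 9 falls. The division with 16 opposite calls also shared 2 rises and 9 falls. Ndn was among the genes that fell over passages, and its level of 67.9 ± 15.5 CPM with vesicles stood between those of P2 and P10 PBS (edgeR fold change 0.89 with vesicles, adjusted p = 0.269). The shared libraries also make the correlation negative without any vesicle effect. Over genes, which are not independent replicates, Pearson's r was -0.335 and Spearman's rho -0.193. Simulated libraries without an effect of passage or vesicles gave r between -0.553 and -0.476 and a covariance between -0.0766 and -0.0607, which includes the observed covariance of -0.0722. They were drawn independently of one another, whereas P10 EV and P10 PBS libraries of equal number correlated at 0.138 to 0.37. The simulated covariance is therefore no exact baseline. With the P10 PBS libraries divided, r lay between -0.19 and 0.0486. Of the 149 genes called at P10 PBS against P2, 122 had the opposite sign with vesicles (81.9%). In the divided libraries 60.5% to 82.4% of the 4 to 74 genes called there did. This share was not stable. Leave-one-out fits ranged from 565 of 1206 called genes without P2 replicate 1 to 66 of 72 without P10 PBS replicate 4. Without the 4 libraries with liver transcripts it was 1011 of 2320.

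**Figure D3:**
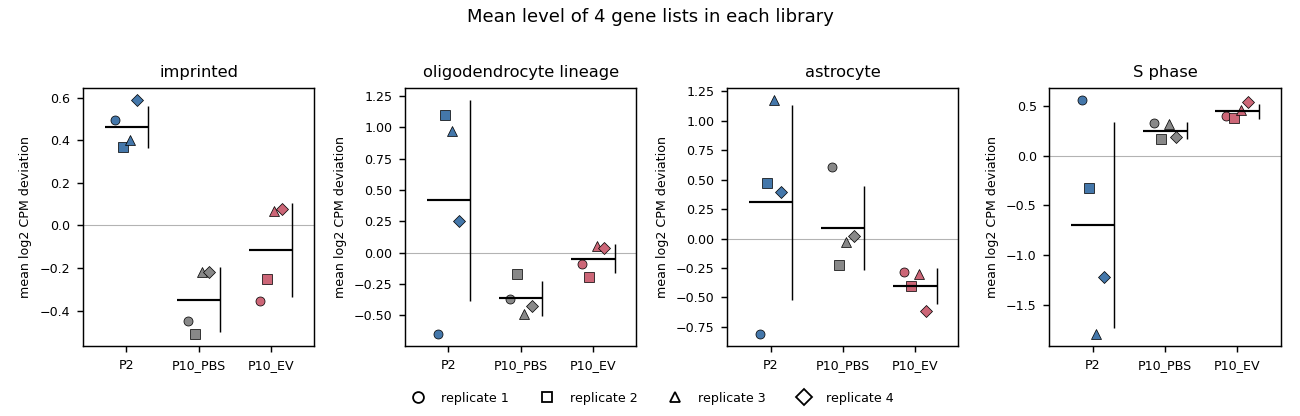
Mean deviation of the genes of 4 lists from their mean over all libraries (log2 CPM, vertical axis) in each of the 12 libraries, by group. The S phase score lay between -1.80 and 0.563 at P2 and between 0.171 and 0.542 in the late libraries, and the imprinted score lay between 0.37 and 0.59 at P2 and below 0.08 in the late libraries.

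The comparison of P10 EV with P2 asks what still differed from early cultures after vesicle treatment. Pmepa1 (ENSMUSG00000038400; chromosome 2, 173224458 to 173276533), a membrane protein that is induced by TGF-beta and restrains SMAD signals, rose from 5.3 ± 1.21 CPM at P2 to 32.6 ± 6.66 CPM (2.62 ± 0.30, adjusted p = 0.00373, n = 4 each), against 8.89 ± 3.81 CPM at P10 PBS. Its relative Ldlrad4 rose from 5.39 ± 2.43 to 18 ± 3.23 CPM (1.73 ± 0.29, adjusted p = 0.0261), against 5.41 ± 1.17 CPM at P10 PBS. Spats2l rose from 21.6 ± 4.92 to 53.6 ± 3.14 CPM (1.31 ± 0.16, adjusted p = 0.00417), and further rises were those of St6gal2 (2.14), Frk (1.74), Pcgf2, a Polycomb protein (1.38), Iqgap2, a scaffold of the cytoskeleton (1.36), and Pcyt1b, of phosphatidylcholine synthesis (1.31). Ndn and Grb10 remained lower than at P2, with fold changes of -1.12 and -4.75, as did Emx2 (-1.19), Lhx2 (-0.98) and Magel2 (-3.92). Hoxa5 was called with 1 pooled count at P2 and 50 at P10 EV. With a block on replicate number the adjusted p was 0.0613 for Ldlrad4, 0.0641 for Pcgf2, 0.0756 for Iqgap2, 0.0574 for Magel2 and 0.0745 for Lhx2.

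The astrocyte and extracellular matrix lists were lower than at P2, with 3 called genes of 34 and 2 of 49. Slc1a2, a glutamate transporter of astrocytes, fell from 764 ± 421 to 255 ± 17.8 CPM (-1.58, adjusted p = 0.0469), Sparcl1, a secreted astrocyte protein, from 309 ± 206 to 23.8 ± 12.4 CPM (-3.70), and Agt (angiotensinogen) from 30.4 to 3.35 CPM (-3.17). Of 34 astrocyte genes, 3 fell and 31 did not pass (9 fell adjusted over the list alone), with a median of -0.63 (adjusted p = 1.25e-07; adjusted p = 0.507 with an estimated correlation). Its score was -0.812 in P2 replicate 1 and 0.475, 1.18 and 0.392 in P2 replicates 2, 3 and 4, against -0.615 to -0.285 in P10 EV. Fbln2 fell to 222 ± 42.9 CPM (-1.44 ± 0.17, adjusted p = 0.00373), and Col4a1, a collagen of basement membranes, from 47.8 to 13.9 CPM (-1.79). These were the 2 falls among 49 extracellular matrix genes, of which 47 did not pass (10 fell adjusted over the list alone). The extracellular matrix list had a median of -0.27 and an adjusted p of 0.00104 (adjusted p = 0.507 with an estimated correlation), and was not called without P2 replicate 2 (adjusted p = 0.206). Mmp2 (-2.35), Mmp14 (-2.51) and Gdf15 (-1.71) fell among 28 genes of the SASP list (median -0.40, adjusted p = 0.0131; adjusted p = 0.443 with an estimated correlation), which was not called without P2 replicate 2 (adjusted p = 0.0858) or without the 4 libraries with liver transcripts (adjusted p = 0.0872). Cd82, a tetraspanin (-3.96), Clec3b (-3.37), Dhh, a hedgehog ligand (-3.13), Thrsp, a regulator of lipid synthesis (-3.07), Cnp, a myelin enzyme (-1.59), and Dpysl3 (-0.82) also fell. With a block on replicate number the adjusted p was 0.102 for Slc1a2, 0.0798 for Sparcl1, 0.0837 for Agt, 0.081 for Mmp2, Dhh and Cnp, 0.0785 for Thrsp and 0.0858 for Dpysl3.

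The S phase and G2/M lists were higher than at P2, where the libraries were unequal. S phase genes lay above 0 in 39 of 40 cases (median 0.89, adjusted p = 1.7e-19; adjusted p = 0.443 with an estimated correlation) and G2/M genes in 52 of 53 (median 0.51, adjusted p = 1.9e-14; adjusted p = 0.507 with an estimated correlation), with 0 members called by edgeR in either list. P2 replicate 1 had an S phase score of 0.563, above the 0.382 to 0.542 of the P10 EV libraries, and P2 replicates 3 and 4 had -1.80 and -1.23; the G2/M scores of these 3 early libraries were 0.466, -1.04 and -0.553. The imprinted list fell with 3 called genes of 26 (9 adjusted over the list alone), a median of -0.24 and an adjusted p of 0.000818, or adjusted p = 0.1 with an estimated correlation. The neuronal lineage list fell with 1 called gene of 32 and a median of -0.36 (adjusted p = 0.00124; adjusted p = 0.24 with an estimated correlation). HIF targets had a median of -0.49 (adjusted p = 0.00311; adjusted p = 0.781 with an estimated correlation), and without P2 replicate 2 the HIF targets list was not called (adjusted p = 0.849). The oligodendrocyte lineage list fell with a median of -0.32 (adjusted p = 0.0217; adjusted p = 0.631 with an estimated correlation) and was not called without P2 replicate 2 or P2 replicate 3 (adjusted p = 0.519 and 0.0978). The neural stem cell list fell with a median of -0.12 and 1 called gene of 29 (camera adjusted p = 0.0369, or 0.309 with an estimated correlation). The senescence list fell with a median of -0.42 and 0 called genes of 16 (camera adjusted p = 0.024, or 0.271 with an estimated correlation). Class I histocompatibility genes (median -0.48, adjusted p = 0.0666) and TGF-beta and BMP targets (median -0.44, 1 rise and 1 fall, adjusted p = 0.457) were not called. Without the 4 libraries with liver transcripts the imprinted, neuronal lineage, HIF targets and extracellular matrix lists were not called (adjusted p = 0.0601, 0.0629, 0.194 and 0.0964). That fit held only replicates 3 and 4 of P2.

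At P10 EV against P2, 28 genes rose and 66 fell (76 of these 94 by a fold of at least 2). The libraries of both groups did not overlap in 1448 genes, 9.02% where interchangeable libraries would give 2.86% on average. The spread of this share over splits was not computed. Of the 94 calls, 17 rises and 33 falls were also called at P10 PBS against P2, and 0 genes were called in opposite directions. Both comparisons share the 4 P2 libraries, which gives overlap in the same direction without a common change. Independent lists would share 0.11 and 0.36, and 20 simulated sets without any effect had at most 1 edgeR call per comparison, which gives no baseline for the overlap. With the P2 libraries divided between both comparisons in 6 ways, 0 to 5 rises and 3 to 19 falls were shared. These divided edgeR fits held 13 to 2290 calls for P10 PBS and 4 to 3176 for P10 EV. Between 0 and 2 genes were called in opposite directions there. DESeq2 called 924. The count was 2821 without P2 replicate 1, 29 without P2 replicate 3, 17 without P2 replicate 4, 13 without P10 EV replicate 1, 8 without P10 EV replicate 2, 23 without P10 EV replicate 3 and 10 without P10 EV replicate 4. Of 28 named calls, 25 were lost without P10 EV replicate 1, 25 without P10 EV replicate 2, 24 without P10 EV replicate 4, 21 without P2 replicate 4, 18 without P10 EV replicate 3, 17 without P2 replicate 3 and 4 without P2 replicate 2, and those of Pmepa1, Spats2l and Fbln2 were kept whichever library was left out. No KEGG pathway was over-represented (smallest adjusted p = 0.813), and of 41 lists 6 rose and 17 fell, with 0 called with an estimated correlation.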

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

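Both tests of the liver transcripts, the tests of Pmepa1 and Ldlrad4 and the term for the 4 libraries with liver transcripts were chosen only after the result was seen.

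In 18 of 297 groups of 4 libraries (6.06%), over 90 named genes and the measures of library depth and content, 1 library stood far from the other 3; chance sets apart about 1 in 20 groups. In P2 replicate 2, Eno1 lay at 1360 CPM (others 592 to 629), H2-K1 at 78.7 CPM (34 to 34.5), Map2 at 500 CPM (672 to 696) and Hoxa5 at 0.0731 CPM (others 0). The Hoxa5 value is 1 count, which stands apart from 0 by rule and says nothing about the library. P2 replicate 1 held Smad2 at 41.5 CPM (22.8 to 24.2) and Pcgf2 at 2.42 CPM (4.04 to 4.46). P10 PBS replicate 1 held Igfbp2 at 1780 CPM (988 to 1020), Psap at 866 CPM (607 to 636) and Nr2f1 at 68.3 CPM (80 to 81.8). P10 PBS replicate 2 held Slc1a3 at 1430 CPM (2180 to 2370), St6gal2 at 54.4 CPM (32.3 to 34) and H2-Q4 at 3.12 CPM (6.64 to 7.55), and P10 PBS replicate 4 held Bcl11b at 12 CPM (7.99 to 8.33). P10 EV replicate 4 held the cell-cycle genes Mki67 at 861 CPM (468 to 515) and Top2a at 813 CPM (600 to 620) and the receptor phosphatase Ptprz1 at 3510 CPM (2450 to 2590). In P10 EV replicate 1 Nr2f1 lay at 61.3 CPM (71.6 to 73.3), and in P10 EV replicate 2 Zbtb20, a factor of hippocampal identity, lay at 305 CPM (39.4 to 52).

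Transcripts of liver stood out in P2 replicates 1 and 2, P10 PBS replicate 1 and P10 EV replicate 1, where 34 liver genes summed to 91.9 to 113 CPM against 3.54 to 7.99 CPM elsewhere; 1 of the 34 reached 1 CPM in the mean of the other libraries. A candidate source is RNA or reads of 1 liver sample carried into the 4 libraries: counts of the liver genes stood in nearly 1 ratio across them (chi-square per degree of freedom 1.03). Expression by the cultures of replicate 2 themselves was argued against by its late libraries, which held at most 0.0394 of the liver CPM of P2 replicate 2, counted without Itih3, the gene that other libraries expressed. The source of these transcripts stays open.

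Imprinted genes were lower at P10 PBS than at P2. Whatever put liver transcripts into 4 libraries did not account for this, since 5 of 5 called genes kept an adjusted p under 0.05 with a term for the 4 libraries. With the oligodendrocyte and astrocyte scores as covariates, the median of the 5 genes was -2.0 instead of -2.50 and 3 stayed called (Ndn, Grb10 and Magel2); the fold of Mkrn3 went from -1.03 ± 0.19 to -0.76 ± 0.23 and that of Cdkn1c from -2.50 ± 0.49 to -1.29 ± 0.56. Only the oligodendrocyte and astrocyte scores were used as covariates, and they differ between the groups. A different mix of cells at P2 and a change within the cells therefore cannot be told apart for any of the 5 genes. Passage number, which the design names, stays open as an untested explanation.

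Pmepa1 and Ldlrad4, chosen after their values were seen, were higher in each of the 4 P10 EV libraries than in any of the 4 P10 PBS libraries (fold changes 1.87 ± 0.29 and 1.73 ± 0.29; edgeR adjusted p = 0.257 and 0.264, or 0.178 and 0.392 with a block on replicate number; DESeq2 adjusted p = 4.57e-06 and 3.79e-05, from a test that called 36 unchanged genes among 146 calls on simulated data of this layout). A term for the 4 libraries with liver transcripts could not test them as the source, as it marks 1 library in each group; in its place the 4 libraries were left out, and the smaller fold change was still 1.735, which argues against that source. Of 35 splits of the libraries 2 held as many genes of this strength, the real one with 3 and one with 6 that follows a structure of the samples, the cultures with Xist against those with Y-linked transcripts; of the 8 splits that part all 4 pairs of equal number the real one held 3 and the highest other 1, and 8 splits are too few for a share under 0.05. Both genes answer TGF-beta signals, so delivered SMAD proteins may be a source, but the fixed list of TGF-beta and BMP targets had a median of -0.295, with members on both sides of 0, which leaves this open. Skil, a further target, had a fold change of 0.37 (adjusted p = 0.764) and Smad7 -0.03 (adjusted p = 0.991).

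For the counts of called genes, all 35 splits of the libraries were refitted. At P10 PBS against P2, 1 of 35 splits, the real one with 149 genes, gave as many, and the highest other gave 6; at P10 EV against P2, 1 of 35 gave the 94 genes and the highest other gave 1. Over all splits a share of 1 in 35 would exclude chance only if libraries of equal replicate number were exchangeable with the others. Their shared culture codes and matching sex-linked transcripts go against this, so chance was not excluded. Of the 8 splits that part all 4 pairs of equal number, the highest other gave 6 and 0, and 8 splits are too few for a share under 0.05. At P10 EV against P10 PBS the real count was 0, which all 35 splits reach whatever the data, so this count says nothing about chance; the highest other gave 1.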

How the results depend on the processing

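The term for the 4 libraries with liver transcripts, their omission and the term for sex were chosen only after the result was seen. Their omission left only replicates 3 and 4 in P2. For P10 PBS against P2 (149 genes), DESeq2 called 592, the 8 libraries alone 38, the liver term 352, omission of the 4 libraries 2320, the sex term 252, and leave-one-out fits 41 to 1206. For P10 EV against P10 PBS (0 genes), DESeq2 called 67, the 8 libraries alone 2, and leave-one-out fits 0 to 1. For P10 EV against P2 (94 genes), DESeq2 called 924, the 8 libraries alone 30, the liver term 238, omission of the 4 libraries 3335, the sex term 167, and leave-one-out fits 8 to 2821. A block on replicate number gave 167, 0 and 67 genes. Genes called in opposite directions (0) were 29 by DESeq2 and 0 to 1 in leave-one-out fits. Their correlation of -0.335 was -0.205 on FPKM, -0.453 without a filter, -0.22 without the 4 libraries, -0.059 with P10 PBS divided, and -0.489 to -0.218 in leave-one-out fits. Of the called lists, at P10 PBS against P2 (17) 3 were called with an estimated correlation, 3 by fry, 11 with the liver term and 11 to 19 in leave-one-out fits; with vesicles (16) 0, 0 by fry and 14 to 20; at P10 EV against P2 (23) 0, 6 by fry, 13 without the 4 libraries and 14 to 26. The cause was not tested. Over 161 pairs of a named gene and a comparison, 2473 alternative values kept their direction and side of the threshold, 327 lost the call, 32 gained it, 65 moved without a call, and 0 reversed. Of the 161 pairs 60 were called in the main fit, and only the values of these 60 could lose a call. At these depths and 4 libraries per group, edgeR recovered 3% to 4.5% of 1.5-fold changes on simulated data and DESeq2 14.9% to 19.4%.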

Other observations

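All tests of single genes here were chosen only after the result was seen. Counts of Hox genes were higher in both late groups, and 2 homeobox genes of the midbrain were called higher at P10 PBS against P2. Over 29 Hox genes, which pattern the posterior axis, the pooled counts were 17 at P2 (2 to 6 per library), 251 at P10 PBS (39 to 121) and 185 at P10 EV (37 to 58). En2, an engrailed homeobox gene of midbrain and cerebellum, lay at 1.79 ± 1.31 CPM at P2, 16.1 ± 11.1 CPM at P10 PBS and 9.92 ± 4.94 CPM at P10 EV (3.15 at P10 PBS against P2, adjusted p = 0.0318). In the same comparison Dmbx1, a homeobox gene of the midbrain, rose by 2.56 (adjusted p = 0.0153). Its level was low, with a mean of 0.231 CPM at P2 and 1.42 CPM at P10 PBS. En1 and Gbx2, of the midbrain-hindbrain boundary, had fold changes of 2.54 and 2.09 and were not called by edgeR (adjusted p = 0.1 and 0.088).

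With vesicles, further genes differed without passing the edgeR test, most of them with separate groups. Of all tested genes 7.58% had separate groups here, where interchangeable libraries would give 2.86% on average. The genes named were picked after their values were seen, so their separation is no support. Ndn lay at 54.2 to 83.1 CPM at P10 EV against 33.2 to 39.8 CPM at P10 PBS (0.89, adjusted p = 0.269; DESeq2 adjusted p = 0.000473). Igf2bp3, an RNA-binding protein of embryonic cells, lay at 44.3 CPM at P2, 10.8 CPM at P10 PBS and 31.6 CPM at P10 EV (1.54, adjusted p = 0.399). Gpd1, which links glycolysis to lipid synthesis, lay at 66.4 ± 38 CPM at P10 PBS and 15.8 ± 3.73 CPM at P10 EV (-2.07, adjusted p = 0.269), and its groups overlapped. St6galnac5, a sialyltransferase, had a fold change of -1.63 (adjusted p = 0.269), and Wls, which escorts WNT proteins to the cell surface, lay at 118 ± 11.2 and 65.6 ± 10.3 CPM (-0.85, adjusted p = 0.269). Zbtb20 was at 252 ± 27.6 CPM at P10 PBS and 112 ± 129 CPM at P10 EV (-1.17, adjusted p = 0.777), and its groups overlapped. P10 EV replicate 2 lay at 305 CPM, above the mean of P10 PBS, and the other 3 P10 EV libraries at 39.4 to 52 CPM; without it the fold change of Zbtb20 was -2.41 (adjusted p = 0.6).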
